A study of Mus musculus with 31 samples.

How the data were processed

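RNA from the medial prefrontal cortex (mPFC) and the nucleus accumbens (NAc) of adult female C57BL/6J (C57) and DBA2/J (DBA) mice was measured on 31 one-colour Agilent mouse arrays. Per the labels, repeated cross-fostering (RCF) meant that whole litters were moved each day to another dam, from postnatal day 1 to day 4, until they reached the adoptive mother who kept them, 4 in all. Control litters were picked up daily and returned to their own mother. Mice were weaned on day 28 and used at 12 weeks, with at most 2 animals per cage or litter. Samples with an RNA integrity number under 8.0 were discarded, and 200 ng RNA per sample was labelled with Cy3.

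The deposited scanner files hold an intensity for each of 62976 spots per array, written by Agilent Feature Extraction 10.7.3.1 as a background-subtracted and spatially detrended signal with no normalization between arrays. Per the file headers, the other columns used are the median spot and background intensity and the yes-or-no marks of each spot for saturation, outliers and signal well above background. The deposited series matrix holds log2 values of 30067 probes; each column was tested against the files and equals the log2 signal of exactly 1 scanner file plus 1 constant, and all 31 columns share the same 75th percentile, 11.4303. The authors' rule for keeping those probes is not stated, but 30056 of them, and no other probes, were well above background on all 31 arrays. The authors name limma without saying for what.

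The scanner files and the matrix disagree about which array belongs to which sample. For 29 of 31 samples the matrix column equals the scanner file listed with another sample, and for 27 of these the file's group differs. The scanner files are listed in the order of their slide positions, while the matrix columns carry sample names, so each array was given the sample of the matrix column it equals (lowest correlation with its own column 0.999996, highest with any other 0.998). The choice was made after the values had been seen. It was checked on markers of strain (Glo1 and Gabra2 minus Gpnmb), tissue (striatal minus cortical list) and sex (Xist): 2 arrays then lay on the wrong side of the strain midpoint and 5 of the tissue midpoint, against 16 and 15 with the files as listed. The files as listed were run as an alternative for all 14 comparisons and the Xlr family. With the matrix reading, each of the 4 slides, each scanned on a day of its own, held 1 strain and 1 tissue with both treatments. Slide therefore cannot be told apart from strain or tissue in comparisons of those, whereas RCF and control shared a slide but sat mostly in different slide columns.

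In 4 pairs of arrays of 1 group, the spread of differences between arrays was 1.04 to 1.22 times the spread between spots of 1 array, over probes printed at least 5 times; in the other pairs of the 45 it was 2.01 to 5.91 times. Each of the 4 pairs (C57 NAc control 1 and 3, C57 NAc control 2 and 4, DBA mPFC control 2 and 4, DBA mPFC RCF 1 and 3) was averaged and counted as 1 sample, by a limit of 1.5 set after the ratios were seen. That left 27 samples in 8 groups. For 6 of the 27, strain, tissue or sex markers lay on the other side of the midpoint of all arrays (samples in doubt). These were kept, and every count was also run without them.

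The value analysed was the log2 signal minus the array's 75th percentile. A probe was tested if it was no control, was well above background on at least 3 arrays of at least 1 group, and was marked an outlier on at most 50% of arrays. This kept 43414 of 55681 probes. Probes were named through the RefSeq accessions in the files (28026 probes, 21154 symbols). The file headers give an older genome build than the gene table used for names, so no coordinates are given. A gene was represented by its brightest probe, which left 30163 features, 17895 of them with a gene symbol; 16685 of these are called named genes here, the others being predicted or clone names. Array depth is signal over background: 59.4% to 82.4% of probes were well above background per array, and the number of samples limits the precision.

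Differences were tested with limma 3.58.1 (moderated test with intensity trend) in R 4.3.3, in 1 model with 8 group means for all 14 comparisons, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Unadjusted p counts use the same threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. Where a gene was not well above background on any array of 1 group, the fold is given as a lower bound, or not given if only 1 of 4 arrays of the other group was. For genes so placed in an interaction or average, no value is given, and values of the Xlr family in the C57 mPFC are treated the same way. The fitted model, gene lists, comparisons and naming rule were chosen before the data were examined; the averaging of near-duplicates, the array assignment and the samples in doubt were not. The plan had assumed slides of 1 treatment, which the assigned arrays do not bear out.

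Named genes are, per comparison, the 10 largest rises and the 10 largest falls among named genes past the threshold whose groups do not overlap; where fewer than 5 genes passed, the 5 with the smallest p are given as values. To these were added up to 4 members of each fixed list and all measured Xlr members. A few genes that the rule names are not reported here. The 23 gene lists held markers of astrocytes, oligodendrocytes, microglia, vessels and meninges, blood, choroid plexus and ependyma, cortical excitatory neurons, striatal projection neurons, interneurons and septum, and genes of dopamine, noradrenaline and serotonin, opioid and endocannabinoid, glutamate, GABA and stress peptide signalling, glucocorticoid receptor targets, immediate early genes, chromatin and DNA methylation, imprinted genes, cytosolic ribosomal proteins, oxidative phosphorylation subunits and the Xlr family. Lists were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry (statmod 1.5.0), adjusted over the lists of a comparison. The Xlr family was also adjusted over the list alone. Xlr4a, Xlr4b and Xlr3b were put to an exact two-sided test over all regroupings of the DBA samples within tissue.

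On simulated data with 200 changed genes of 30163, limma recovered 48% to 57% of changes of 1 log2 unit and 76% to 82% of changes of 2 in the 6 comparisons tried, with 4 to 11 false calls and none with the wrong sign. The simulated noise was independent between genes and held no samples in doubt, so these rates do not describe the real samples. Alternatives tried were quantile normalization; normexp background correction (offset 50) with quantile normalization, from median spot intensity because the planned mean intensity is not among the columns; no filter and a stricter filter (41798 probes); the median over a gene's probes; the authors' matrix values; array weights; only the groups compared; the replicate number as a block; leaving out each sample; and, added after seeing the data, all 31 arrays as separate replicates, files as listed, leaving out the samples in doubt, and the tissue marker score as a covariate.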

Results

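Gene expression was measured on 31 arrays from female mice of 2 strains, C57 and DBA, in 2 brain regions, the mPFC and the NAc, after RCF or control handling in the first days of life. After near-duplicate arrays were averaged, the C57 mPFC had 3 control and 4 RCF samples, the C57 NAc 2 and 4, the DBA mPFC 3 and 3, and the DBA NAc 4 and 4. Between 59.4% and 82.4% of the probes of an array were well above background. The series title names the X-linked gene Xlr4 and vulnerability to cocaine. Values are log2 signal relative to the array's 75th percentile, changes are differences of group means ± the standard error of the limma model, and genes are named as the array annotation names them.

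Marker genes placed 21 of the 27 samples with their labels and 6 on the other side of a midpoint. The mean of Glo1 and Gabra2 minus Gpnmb, genes known to differ between these strains, had a median of 6.33 in C57 samples in place and 12.02 in DBA samples in place. It was 5.36 in DBA mPFC control 1 and 7.26 in DBA NAc control 4. DBA mPFC control 1 also had Xist, the RNA that silences an X chromosome in female cells, at −5.87, against −0.28 or more elsewhere. Striatal minus cortical markers had medians of −0.41 in the C57 mPFC and 4.79 in the C57 NAc in place. This score was 3.14 in C57 mPFC control 3 and 3.55 in C57 mPFC RCF 1, and it was −1.40 in C57 NAc control 1 and 3 (1 sample on 2 arrays) and −0.86 in C57 NAc RCF 1. Each of these 4 lay nearer to the other tissue than to its own.

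**Figure D1:**
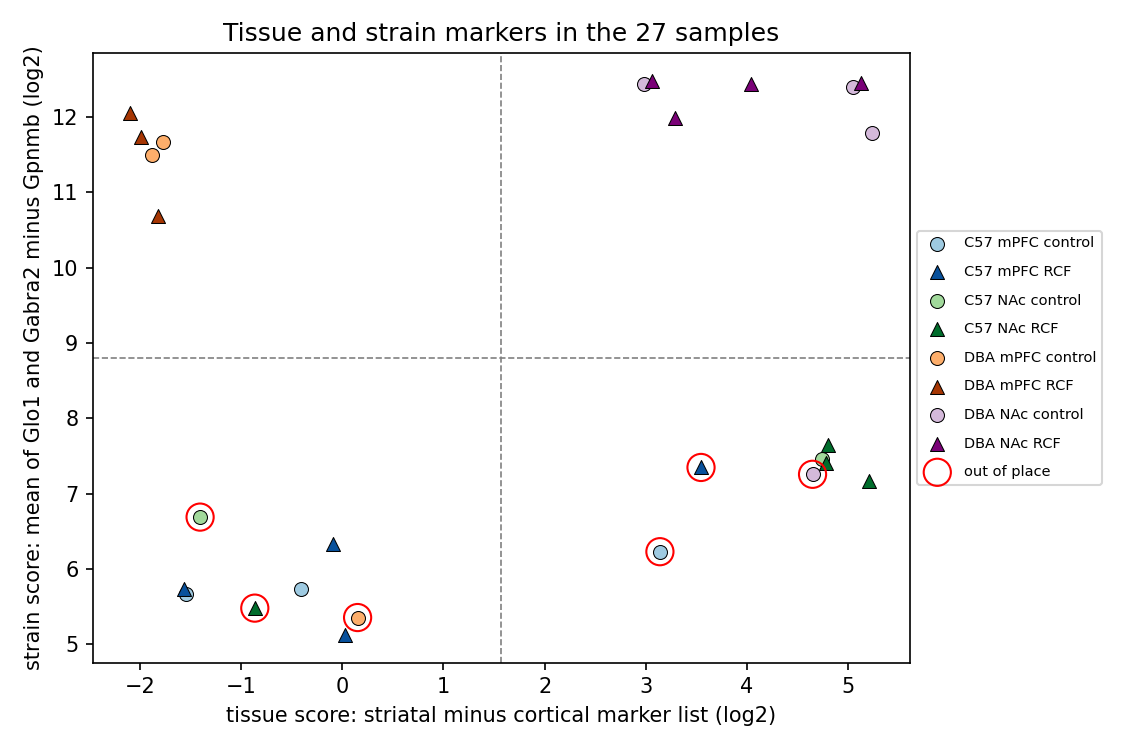
Striatal minus cortical marker score (horizontal, log2) against strain marker score (vertical, log2) of the 27 samples; colours and shapes give the group, dashed lines the midpoints (1.57 and 8.81), red rings the 6 samples on the other side of a midpoint or with low Xist. The 2 ringed samples with DBA labels lie below the strain midpoint, at 5.36 and 7.26.

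Xlr4a and Xlr4b, members of the X-linked lymphocyte-regulated family, were higher on average in RCF than in control DBA mice in both regions, by less than the spread between samples allowed limma to call. Xlr4a differed by 1.35 ± 0.73 in the DBA mPFC and by 1.24 ± 0.63 in the DBA NAc, and Xlr4b by 1.25 ± 0.68 and 1.11 ± 0.58. The second Xlr4a probe differed by 0.51 ± 0.49 in the DBA mPFC and 1.14 ± 0.42 in the DBA NAc. In the NAc, Xlr4a was −2.34 ± 0.42 (SD, n = 4) in RCF and −3.58 ± 1.13 (SD, n = 4) in control samples, and in the mPFC −3.02 ± 1.45 (SD, n = 3) and −4.37 ± 1.29 (SD, n = 3). In C57 mice the differences were 0.50 ± 0.68 in the mPFC and −1.11 ± 0.77 in the NAc for Xlr4a, and 0.19 ± 0.63 and −1.46 ± 0.72 for Xlr4b. The remaining 4 of the 6 members measured (Xlr, Xlr3a, Xlr3b and Xlr5a) differed by −0.37 to 0.70 in the DBA samples and by −0.69 to 0.64 in the C57 samples, apart from Xlr3a and Xlr5a in the C57 mPFC. For each of these, 1 of 4 RCF arrays and no control array was well above background, so no fold is given.

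The Xlr4a differences depended on samples and processing. In each region 1 DBA control sample carried C57 markers, and without these the Xlr4a difference was 2.06 in the mPFC and 1.62 in the NAc. It was smaller in the mPFC without RCF 2 (0.74) or control 2 and 4 (0.80), and in the NAc without control 3 (0.81). With normexp it was 0.67 and 0.60.

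No Xlr member passed over all features or adjusted over the list alone in any comparison of RCF with control within a group. Over the list alone, limma gave Xlr4a an adjusted p = 0.233 in the DBA mPFC and an adjusted p = 0.214 in the DBA NAc. Over all 1400 regroupings of the DBA samples within region, the mean Xlr4a difference of 1.30 had an exact two-sided p of 0.0486 and the Xlr4b difference of 1.18 one of 0.0286, each 0.0729 after adjustment over the 3 genes tested so. Xlr3b had an exact p of 0.16. The interaction of strain and treatment in the NAc was 2.35 ± 1.00 for Xlr4a and 2.56 ± 0.92 for Xlr4b (limma, over the list alone: adjusted p = 0.083 and adjusted p = 0.0658). The only 2 Xlr values past the threshold concerned Xlr5a in control mice, which was at least 5.70-fold higher in DBA than in C57 mPFC (adjusted p = 0.000481) and lower in DBA NAc than in DBA mPFC (change −3.12, adjusted p = 2.4e-05, with 1 of 4 NAc arrays well above background). Xlr5a was well above background on none of the 3 C57 mPFC control arrays. DBA mPFC control 1, which carried C57 markers, had Xlr5a at −3.1, like the other DBA mPFC samples of both treatments (−3.9 to −3.3). All of these shared 1 slide, so for Xlr5a a slide difference cannot be told apart from one of strain or region. Probes of this family match near-identical transcripts, so a value cannot be assigned to 1 member with certainty.

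**Figure D2:**
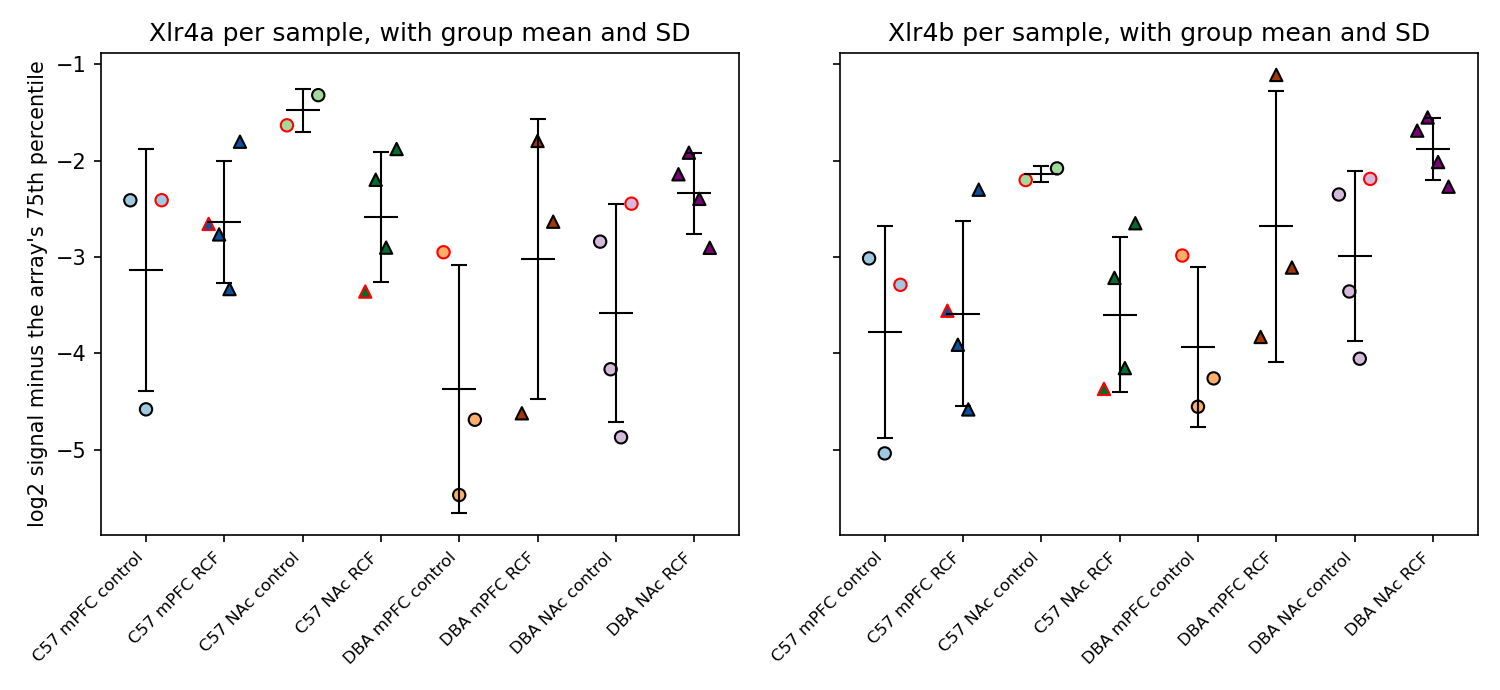
Xlr4a (left) and Xlr4b (right) per sample, as log2 signal minus the array's 75th percentile, by group; circles are control and triangles RCF samples, bars the mean ± SD, and red outlines mark the 6 samples in doubt. The 4 DBA NAc RCF samples lay between −2.91 and −1.92 for Xlr4a, and the control samples between −4.87 and −2.45.

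In the C57 NAc, 22 features were higher and 157 lower in RCF than in control mice, 114 of the 179 being named genes. The lower genes included Abca17, an ABC transporter, by −2.11 ± 0.46, Acap1, a GTPase-activating protein for Arf6, by −1.82 ± 0.29 (adjusted p = 0.0114), Oas1d, of the oligoadenylate synthetase family, by −1.69 ± 0.31, and Hs2st1, a heparan sulfate sulfotransferase, by −1.55 ± 0.32. Golt1a, Vax2, Gxylt2, Arhgap26, Ralgps1 and Fat2 were lower by −1.91 to −1.56. Acap1 was −4.90 ± 0.36 (SD, n = 4) in RCF and −3.08 ± 0.31 (SD, n = 2) in control samples. The largest rises were those of Pip4p1, a phosphoinositide phosphatase (1.93 ± 0.39), Kcnj13, a potassium channel of the choroid plexus (1.51 ± 0.34), Oacyl (1.38 ± 0.32), Tacr2, the neurokinin A receptor (1.33 ± 0.29), and Pdzrn3 (1.33 ± 0.31). Iah1, Usp42, Tmem184c, Snapc5 and Dynlt3 rose by 0.65 to 0.78.

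Of 38 chromatin genes, 3 fell in the C57 NAc and none rose: the histone H3 lysine 9 methyltransferases Ehmt1 (−1.47 ± 0.29) and Suv39h2 (−1.45 ± 0.29) and the deacetylase Hdac7 (−0.92 ± 0.21). The list as a whole did not pass (adjusted p = 0.075 by camera). The 25 striatal projection neuron markers were all higher in RCF by value, with a median of 1.08, and no single member passed. As a list they passed with the preset correlation (adjusted p = 0.00509) but not with an estimated one (adjusted p = 0.934 with an estimated correlation), nor without the samples in doubt (adjusted p = 0.0708). Tissue markers differed within both groups: 1 of the 2 control samples and 1 of the 4 RCF samples carried the cortical marker profile.

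In all 179 features every RCF sample lay on 1 side of both control samples. Over all features 17.8% did so, against 13.3% expected by chance with 2 and 4 samples. The count rested on single samples: it was 6 without control 1 and 3, 1347 without control 2 and 4, 9 without RCF 1, 52 without RCF 2, 183 without RCF 3 and 0 without RCF 4. All 179 kept their sign when 1 sample was left out, which had to be so because their groups did not overlap. The median change, 1.37 as reported, was 0.92 without control 1 and 3, 1.83 without control 2 and 4, and 1.26 to 1.49 without 1 RCF sample. A wider range without a control sample follows from the group sizes of 2 and 4. Without 1 control sample, or without the samples in doubt, the 1 control sample left was assumed to vary like the other groups. The count of features also depended on the settings. It was 7 without the samples in doubt, 2 of them shared with the 179, 43 with the tissue score as a covariate (median change 1.31), 301 with quantile normalization (28.6% of them higher, against 12.3%), 347 with normexp and 0 when the 2 groups were fitted alone.

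In the C57 mPFC, limma called 0 features between RCF and control mice, with 745 at an unadjusted p under 0.05. The smallest p values belonged to Dag1, the dystroglycan of the extracellular matrix receptor (−0.51 ± 0.11, adjusted p = 0.457), Taf7l2, the cadherin Cdhr5 (−1.67 ± 0.37, 1 of 4 RCF arrays well above background), the ubiquitin ligase Rnf25 (1.15 ± 0.26) and Ccdc71 (0.59 ± 0.14). For Taf7l2, 1 of 4 RCF arrays and no control array was well above background, so no fold is given. None of the 23 lists passed by camera or fry. The count was 12 without control 2 and 11 with array weights.

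In the DBA mPFC, markers of oligodendrocytes, microglia and vessels were lower in RCF than in control mice as lists. None of these lists passed without the samples in doubt, here control 1 with its C57 and male markers. Of 22 oligodendrocyte and myelin markers 19 were lower by value, with a median of −0.47 (adjusted p = 2.78e-06 by camera, but adjusted p = 0.371 with an estimated correlation), among them Opalin (−0.91 ± 0.48) and the myelin protein Mal (−0.95 ± 0.55). Of 20 microglia markers 17 were lower, with a median of −0.14 (adjusted p = 9.08e-05, and 0.371 with an estimated correlation), among them the fractalkine receptor Cx3cr1 (−0.48 ± 0.13), which passed adjusted over the list alone. Vascular and meningeal markers (median −0.19, adjusted p = 0.0001, and 0.495 with an estimated correlation) included Flt1, a VEGF receptor (−0.36 ± 0.13). Immediate early genes (median −0.14, adjusted p = 0.0313) and striatal markers (median −0.54, adjusted p = 0.0308) were lower and the Xlr family (median 0.58, adjusted p = 0.029) higher, none of them with an estimated correlation (adjusted p = 0.722, 0.797 and 0.371).

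Gene by gene, limma called 0 features in the DBA mPFC, with 469 at an unadjusted p under 0.05; fry called 0 lists. The smallest p values were those of Cpd (−0.43 ± 0.11), the cell adhesion molecule Ceacam2 (−0.96 ± 0.25), Cx3cr1, the vomeronasal receptor Vmn1r176 (at least 1.91-fold lower) and Smtn, a smooth muscle protein (−0.53 ± 0.16). Array weights gave 11 features. Control 1 was 1 of the 3 control samples. Its oligodendrocyte score was 2.32, against 1.30 and 1.04 in the other control samples and 0.88 to 1.38 in RCF samples. Without the samples in doubt the oligodendrocyte (adjusted p = 0.676), microglia (0.0547) and vascular lists (0.205) kept their direction but no longer passed (microglia scores of 1.81 to 1.84 in RCF and 1.86 and 2.00 in the other control samples), the immediate early genes and the striatal markers turned to the opposite direction without passing (adjusted p = 0.676 and 0.84), and the Xlr family passed with the preset correlation (0.000107), an estimated one not being run there. The Xlr difference was largest in RCF 2, with a score of −2.47, against −4.01 and −3.62 in the other RCF samples and −4.56 to −3.24 in control samples.

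In the DBA NAc, cortical excitatory neuron markers, immediate early genes and vascular markers were higher in RCF than in control mice as lists, and cytosolic ribosomal proteins lower. Of 23 cortical markers 22 were higher by value, with a median of 0.59 (adjusted p = 0.00274 by camera), among them the vesicular glutamate transporter Slc17a7 (2.38 ± 1.39) and the transcription factor Neurod6 (2.04 ± 1.37). Of 27 immediate early genes 22 were higher, with a median of 0.36 (adjusted p = 0.00409), and of 28 vascular markers 26, with a median of 0.21 (adjusted p = 0.00274), among them the tight junction protein Cldn5 (0.48 ± 0.22). The 84 ribosomal protein genes had a median of −0.06 (adjusted p = 0.00909). With an estimated correlation each of the 4 lists had an adjusted p = 0.904, and fry called none. The cortical and vascular differences were largest in RCF 4, with a cortical score of −0.25 (other RCF samples −2.08 to −1.10, control samples −2.52 to −1.68) and a vascular score of 1.20 (others 0.09 to 0.64, control samples 0.04 to 0.94). Its ribosomal score of 5.40 was the lowest (others 5.51 to 6.04, control samples 5.57 to 5.88), and that of immediate early genes was highest in RCF 2 (−0.25, others −1.62 to −0.61, control samples −1.45 to −0.78). The vascular list no longer passed without the samples in doubt (adjusted p = 0.201). RCF 3 and RCF 4, with control 1, had lower tissue scores (2.98 to 3.29) than the other DBA NAc samples (4.04 to 5.24).

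Limma called 0 features in the DBA NAc, with 607 at an unadjusted p under 0.05. The smallest p values were those of Sprr4, an epithelial envelope protein (1.26 ± 0.28), Taf7l2 (−1.19 ± 0.27, 1 of 4 RCF arrays well above background), the interferon regulatory factor Irf4 (at least 1.71-fold higher), the odorant receptor Olfr910 and Eif4e1b. No control array was well above background for the last 2, and no fold above 1 can be given for them. Leaving out RCF 1 or RCF 2 gave 1 feature.

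Whether fostering acted differently in the 2 strains was tested by the interaction of strain and treatment. Limma called 0 features in either region, with 442 in the mPFC and 2311 in the NAc at an unadjusted p under 0.05. In the NAc, the smallest p values were those of Acap1 (2.22 ± 0.37, adjusted p = 0.133), the nucleotide sugar transporter Slc35d1 (1.41 ± 0.26), Taf7l2, the transcription factor Sp6 (1.47 ± 0.29) and the ubiquitin protease Usp36 (1.10 ± 0.24). In the mPFC they were those of Vmn1r176, the ubiquitin ligase Rnf41 (0.70 ± 0.20), Ccdc47 (−0.61 ± 0.17), Piga (−0.54 ± 0.15) and Dhrs2 (2.36 ± 0.68). No value is given for Taf7l2 and Vmn1r176, since no array was well above background in 2 of the 4 groups. Leaving out 1 sample gave 520 features in the NAc without C57 NAc control 2 and 4, 5 without C57 NAc control 1 and 3, 1 without C57 NAc RCF 3, and 1 in the mPFC without C57 mPFC control 2. In the NAc there were also 7 with normexp and 5 without the samples in doubt.

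The interaction of tissue and treatment likewise gave 0 features by limma in either strain, with 1370 in C57 and 325 in DBA mice at an unadjusted p under 0.05. In C57 mice the smallest p values were those of Nfia, a transcription factor of glial differentiation (−1.37 ± 0.30), Rergl (−1.66 ± 0.38), Sp6 (−1.28 ± 0.30), the sperm calcium channel Catsper4 (−1.30 ± 0.31) and the cohesin regulator Pds5a (−0.88 ± 0.21). In DBA mice they were those of Ceacam2 (1.34 ± 0.34), Olfr93 (no array of the NAc control group well above background, so no value is given), the endothelial receptor Cd93 (0.73 ± 0.22), the nucleosome-binding protein Hmgn5 (0.70 ± 0.21) and Dhrs2 (−2.10 ± 0.66). In C57 mice the count was 43 without NAc control 2 and 4, 5 without NAc control 1 and 3 and 3 without the samples in doubt; in DBA mice it was 1 without NAc RCF 2.

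Averaged over the strains, RCF and control mice differed in 0 features in the mPFC by limma, with 659 at an unadjusted p under 0.05. The smallest p values were those of the sperm metalloprotease Adam24 (no value given, since no control array was well above background), Dag1 (−0.34 ± 0.08), the hepatic lipase Lipc (1.54 ± 0.40), Smtn (−0.40 ± 0.11) and Cpd (−0.27 ± 0.08). For Lipc only 1 of 4 DBA control arrays was well above background, so its value is not a measured fold. Lists of astrocytes (adjusted p = 0.0143), microglia (0.00198), oligodendrocytes (0.00927) and vessels (0.0143) were lower and the Xlr family higher (0.00359), with adjusted p = 0.371 to 0.643 with an estimated correlation. Without the samples in doubt, among them DBA mPFC control 1, the astrocyte (adjusted p = 0.151), microglia (0.111), oligodendrocyte (0.939) and vascular lists (0.549) no longer passed. The count was 3 without C57 mPFC control 2 and 5 with array weights.

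In the NAc averaged over the strains, 1 feature was lower in RCF mice, the transcript ENSMUST00000060215 with no gene symbol, named here after its values were seen (−0.91 ± 0.13, adjusted p = 0.0215). Among named genes the smallest p values were those of Bcl7b, a subunit of a chromatin remodeller (−0.63 ± 0.11, adjusted p = 0.0925), Nfia (−0.84 ± 0.15), the sodium leak channel Nalcn (−0.65 ± 0.12), Fryl (−0.80 ± 0.16) and Tmem184c (0.43 ± 0.09). Striatal markers were higher as a list (median 0.58, adjusted p = 0.0217, and 0.983 with an estimated correlation). Leaving out 1 sample gave 344 features without C57 NAc control 2 and 4, 5 without C57 NAc control 1 and 3, 3 without C57 NAc RCF 2, and 0 without any of C57 NAc RCF 1, 3 or 4, DBA NAc control 1, 3 or 4, or DBA NAc RCF 2 or 4. It was 85 with normexp, 116 with array weights and 5, with 0 shared, without the samples in doubt.

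Control mice of the 2 strains differed widely in the mPFC: 4816 features were higher and 2542 lower in DBA than in C57 mice. Cox17, which carries copper to cytochrome oxidase, was lower by −3.66 ± 0.18 (adjusted p = 1.21e-11). Also lower were Acyp2 (−4.12 ± 1.05), the cadherin Cdh3 (−3.85 ± 0.87), Lhx5 (−3.18 ± 1.16), Iqcf4 (−3.12 ± 0.79) and Lyar (−3.08 ± 0.42), and Abhd3 at least 6.56-fold, Lpcat4 at least 4.57-fold, Bex6 at least 3.49-fold and Arhgap19 at least 2.91-fold. For Cdh3, Lhx5 and Lyar only 1 of 4 DBA arrays was well above background, so these values are not measured folds. Higher in DBA were Stab2, a hyaluronan receptor of endothelium (4.25 ± 1.20), the synaptotagmin Syt10 (3.52 ± 0.61), the chemokine receptor Ccr6 (3.43 ± 1.11) and Serpina1a, an antitrypsin gene (3.08 ± 0.90). The melanocortin receptor Mc1r was at least 11.3-fold, Serpina1d at least 5.77-fold, Mael at least 5.11-fold, Olfr690 at least 3.03-fold, Glis3 at least 2.86-fold and Adam2 at least 2.53-fold higher. The Mc1r bound rested on 1 sample: the DBA mean was −2.26 ± 5.29 (SD, n = 3), and the difference was 0.98 (adjusted p = 0.2 by limma) without DBA mPFC control 3. Stab2, Serpina1d and Mael did not pass either without that sample or without DBA mPFC control 2 and 4.

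By list, 11 of 38 chromatin genes were lower and 3 higher in the DBA mPFC, among them Ehmt1 (−1.10 ± 0.28), Suv39h2 (−0.95 ± 0.28), Hdac3 (−0.92 ± 0.18) and Hdac8 (0.97 ± 0.21); camera gave adjusted p = 0.0118 and fry 0.0188 (adjusted p = 0.371 with an estimated correlation). Of 18 astrocyte markers 4 were lower (Glul, the glutamine synthetase, −0.95 ± 0.18) and none higher (adjusted p = 0.00662). Of 75 oxidative phosphorylation subunits 9 were lower and 6 higher (adjusted p = 0.000194), among the lower ones Ndufb2 (−0.72 ± 0.21). Of 84 ribosomal protein genes 9 were lower and none higher (Rps21, −1.04 ± 0.24; adjusted p = 9.42e-05), but the list's direction turned with quantile normalization (adjusted p = 0.887) and normexp (0.976). Striatal markers were lower as a list with no member past the threshold (adjusted p = 0.0118); 1 of the 3 C57 samples carried striatal markers. With an estimated correlation these 4 lists had an adjusted p = 0.912. Without the samples in doubt the ribosomal (adjusted p = 0.576) and oxidative phosphorylation lists (0.693) no longer passed.

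Groups of 44.3% of all features did not overlap, against 10% expected by chance. Quantile normalization placed 55% of the called features higher, against 65.5%. The count was 4339 without DBA mPFC control 3, 5729 without the samples in doubt, 4894 with the matrix values, of fewer features tested, and 13055 with array weights. Each strain and tissue had a slide of its own, so the groups alone do not tell slide and strain apart. DBA mPFC control 1, with C57 markers, lay on the DBA side for each of the largest rises and falls named, because overlapping groups were left out. Cox17 was −4.71 ± 0.26 (SD, n = 3) in DBA samples, this one included, and −1.05 ± 0.21 (SD, n = 3) in C57. Such genes may follow the slide and not the strain, which was not tested.

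In the NAc, 1833 features were higher and 3351 lower in DBA than in C57 control mice. Lower in DBA were Fggy, a carbohydrate kinase (−5.72 ± 1.44), Iqcf4 (−5.10 ± 0.84), Trim12a (−4.97 ± 1.37), the interferon-inducible gene Mndal (−4.17 ± 0.82), the Nogo receptor partner Lingo1 (−4.00 ± 0.55), the mitochondrial exonuclease Mgme1 (−3.83 ± 0.78), Olfr715b (−3.67 ± 0.75) and Lilra5 (−3.67 ± 0.76), with Lipc at least 4.20-fold and Lpcat4 at least 2.99-fold. For Trim12a, Mndal, Mgme1 and Lilra5 only 1 of 4 DBA arrays was well above background, and for Gabrq and Avp 1 of 4 C57 arrays, so these values are not measured folds. Higher were Stab2 (5.40 ± 1.27), Serpina1a (4.02 ± 0.95), the formyl peptide receptor Fpr2 (3.87 ± 1.02), the synaptic vesicle protein Sv2c (3.55 ± 1.04), Ush1c (3.33 ± 0.98), Ttll2 (2.69 ± 0.87), the GABA receptor subunit Gabrq (2.66 ± 0.92) and Col5a2 (2.57 ± 0.61), with Slpi at least 3.20-fold and Defa38 at least 1.78-fold. Stab2, Serpina1a, Iqcf4 and Lpcat4 had also been among the largest strain differences of the mPFC. Over all features, 705 were higher in DBA in both regions (293 expected by chance), 930 lower in both (282) and 368 opposite (690).

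By list, the NAc of DBA mice had 9 of 84 ribosomal protein genes higher and none lower (Rps23, 0.78 ± 0.22; adjusted p = 2.96e-05) and 2 of 35 imprinted genes higher, Peg3 (1.19 ± 0.37) and Impact (0.72 ± 0.21; list adjusted p = 0.0123). Striatal markers were higher (adjusted p = 0.0123) and cortical markers lower (0.0293) as lists with no member past the threshold, and both turned without the samples in doubt (adjusted p = 0.741 and 0.842), while the imprinted genes no longer passed (0.57); 1 of the 2 C57 samples carried cortical markers. With an estimated correlation these 4 lists had an adjusted p = 0.874. Chromatin genes passed by fry (adjusted p = 0.025) and not by camera (0.284), with Ehmt1 (−1.72 ± 0.29) and Suv39h2 (−1.72 ± 0.29) lower and Hdac8 (1.07 ± 0.23) higher, as in the mPFC. The same 2 C57 NAc control samples enter the fall of Ehmt1 and Suv39h2 with RCF and the strain interaction of chromatin genes in the NAc. These are therefore not separate results. Arginine vasopressin, Avp, was higher by 4.52 ± 1.53 (adjusted p = 0.0443).

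Groups of 36.5% of features did not overlap in the NAc, against 13.3% expected by chance, and quantile normalization placed 46.9% of the called features higher, against 35.4%. DBA NAc control 4, with C57 markers, lay on the DBA side for each of the largest rises and falls named. Lingo1 was −3.7 ± 0.30 (SD, n = 4) in DBA samples, this one included, and 0.30 ± 1.45 (SD, n = 2) in C57. Here too such genes may follow the slide. The count was 855 without C57 NAc control 1 and 3, 2269 without the samples in doubt, 1437 when the 2 groups were fitted alone and 9785 with all 31 arrays as replicates; slide and strain cannot be told apart here either.

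Between the regions of DBA control mice, 3239 features were higher in the NAc and 8318 higher in the mPFC. The NAc had more Lhx8, a transcription factor of cholinergic neurons of the ventral forebrain (8.87 ± 1.87), the calcitonin receptor Calcr (7.33 ± 1.53), Six3os1 (7.03 ± 1.85), the vesicular transporter Slc10a4 (6.42 ± 1.56), neurotensin, Nts (6.37 ± 1.44), Dlk1 (6.05 ± 1.37), Sfta3-ps (6.01 ± 1.55), Clic6 (5.98 ± 1.27), Gbx2 (5.78 ± 1.13) and Dgkk (5.73 ± 1.10). For Lhx8, Calcr, Six3os1, Slc10a4 and Gbx2, as for Peg10, Tacr3, Gbx1 and Nkx2-1 below, only 1 of 4 mPFC arrays was well above background, so these values are not measured folds. The mPFC had more of the vesicular glutamate transporter Slc17a7 (−7.98, adjusted p = 0.00031) and of Neurod6 (−6.87, adjusted p = 0.00108), Hkdc1 (−6.46 ± 1.35), the zinc transporter Slc30a3 (−6.06 ± 1.35), Prdm8 (−5.80 ± 1.33), Myh3 (−5.61 ± 1.10), Neurod2 (−5.24 ± 1.18) and Otop2 (−5.21 ± 1.27), with Prss16 at least 13.4-fold. The median of all features was −0.13 as scaled here and −0.01 with quantile normalization, which also placed 43.5% of the called features higher, against 28%; the camera tests of lists compare with the other features.

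Gene lists separated the regions of DBA mice. Of 25 striatal markers 12 were higher in the NAc and none lower, with a median of 2.28 (adjusted p = 5.67e-08, and 0.444 with an estimated correlation), among them Isl1 (5.07 ± 1.60), Six3 (4.66 ± 1.19) and the adenosine receptor Adora2a (3.57 ± 1.32). Of 23 cortical markers 20 were lower and 1 higher, with a median of −3.14 (adjusted p = 9.54e-05, and 0.448 with an estimated correlation). Of 27 immediate early genes 13 were lower and none higher (adjusted p = 0.0179, and 0.631), among them Bdnf (−3.81 ± 0.82), Nptx2 (−2.85 ± 0.59) and Arc (−2.24 ± 0.58). Of 35 imprinted genes 20 were higher and 3 lower (adjusted p = 1.93e-06, and 0.258), among them Peg10 (5.51 ± 1.08) and Asb4 (3.31 ± 0.91). Of 20 dopamine signalling genes 4 were higher and 2 lower (adjusted p = 0.00173, and 0.444), with Rgs9 (3.11 ± 1.20), the receptor Drd1 (2.66 ± 1.02) and the enzyme Ddc (2.29 ± 0.50) higher and Drd4 (−2.15 ± 0.44) lower. Of 21 GABA genes 9 were higher and 1 lower (adjusted p = 0.0179, and 0.191), among them Gad2 (2.21 ± 0.54) and Slc32a1 (1.98 ± 0.44); the list's mean of 0.55 and its test pointed up while its median was −0.05.

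Neuropeptide and receptor lists held members that went both ways. Of 29 stress peptide genes 10 were higher in the NAc, among them Tacr3 (4.84 ± 1.16) and Cartpt (4.73 ± 1.14), and 7 lower, among them cholecystokinin, Cck (−4.59 ± 1.00), and urocortin, Ucn (at least 4.27-fold; list adjusted p = 0.05 as rounded, under the threshold, and 0.241 with an estimated correlation). Opioid and endocannabinoid genes (4 higher, 6 lower, adjusted p = 0.606) included Penk (3.26 ± 0.99), Oprk1 (2.75 ± 0.80) and Faah (−1.73 ± 0.49), noradrenaline and serotonin genes (3 higher, 6 lower, adjusted p = 0.968) Htr4 (3.42 ± 1.09) and Adra1d (−4.29 ± 0.93), and glutamate receptors (6 higher, 6 lower, adjusted p = 0.294) Grik2 (1.54 ± 0.33) and Gria3 (−1.59 ± 0.38). Of 18 interneuron markers 6 were higher, among them the choline transporter Slc5a7 (4.93 ± 1.32), and 4 lower, among them Vip (−4.56 ± 1.05; list adjusted p = 0.0773). Of 23 glucocorticoid receptor targets 3 were higher and 9 lower (adjusted p = 0.619), among them Zbtb16 (−1.80 ± 0.58). Septal and neighbouring region markers (5 higher, 1 lower, adjusted p = 0.0267, and 0.444 with an estimated correlation) included Gbx1 (5.50 ± 1.36) and Nkx2-1 (5.49 ± 1.38).

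Of the lists of other cell types, 6 of 18 astrocyte markers (adjusted p = 0.0156), 3 of 22 oligodendrocyte markers (0.00242), 9 of 84 ribosomal protein genes (8.51e-09) and 1 of 75 oxidative phosphorylation subunits (0.00242) were higher in the DBA NAc and none lower, with adjusted p = 0.444 to 0.642 with an estimated correlation. Over all 30163 features, 3239 were higher there and 8318 lower. The shares of higher ribosomal and oligodendrocyte genes were near that of all features, and the oxidative phosphorylation share was below it. These counts alone therefore show no rise of the 3 lists. Without the samples in doubt the oxidative phosphorylation list no longer passed (adjusted p = 0.0638). Microglia (1 higher, 5 lower, adjusted p = 0.583), blood (0 and 3, 0.28), vascular (0 and 2, 0.968), choroid plexus (3 and 4, 0.28) and chromatin genes (2 and 4, 0.0567) did not pass by camera. By fry, the cortical, GABA, immediate early, imprinted, interneuron, microglia, blood and noradrenaline and serotonin lists passed. Groups of 45.8% of features did not overlap, against 5.71% expected by chance. The count was 4609 with the tissue score, itself made of these markers, as a covariate, 7587 with the matrix values, of fewer features tested, and 18851 with array weights; region and slide cannot be told apart here.

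**Figure D3:**
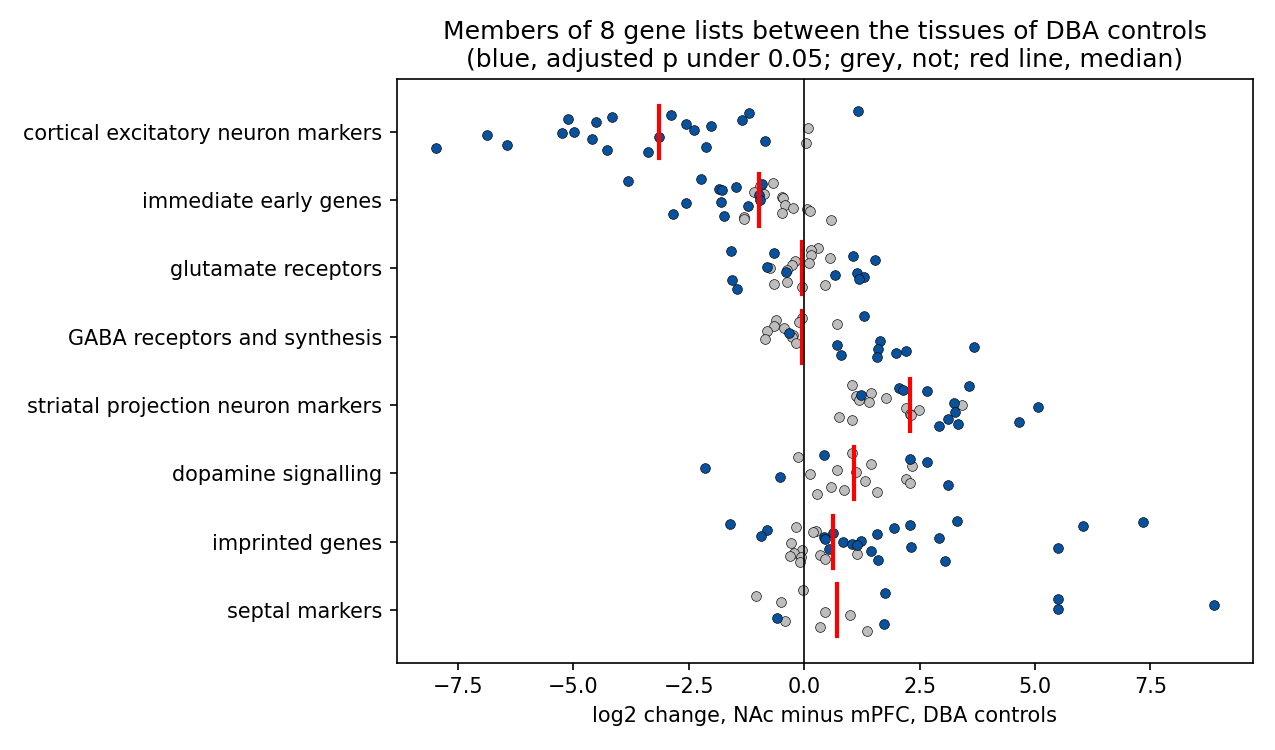
Change between NAc and mPFC of DBA control mice (horizontal, log2) for each measured member of 8 gene lists; blue points have an adjusted p under 0.05, grey points do not, and red lines are list medians. The medians run from −3.14 for cortical to 2.28 for striatal markers.

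Between the regions of C57 control mice, 17 features were higher in the NAc and 13 in the mPFC. Higher in the NAc were Acap1 (1.73 ± 0.30), Catsper4 (1.25 ± 0.25), Sp6 (1.20 ± 0.23) and the telomere enzyme Tnks (1.18 ± 0.22), with the arrestin-related Arrdc5 at least 2.13-fold. For the poly(A) polymerase Papolb, also higher, 1 of 4 NAc arrays and no mPFC array was well above background, so no fold is given. Acap1 was −3.08 in C57 NAc control, −4.81 in C57 mPFC control and −4.90 in C57 NAc RCF samples. The same 2 NAc control samples enter the RCF, tissue and interaction values of Acap1, Catsper4 and Sp6, so these are not separate results. Lower were Arpc1b, of the actin-branching Arp2/3 complex (−0.88 ± 0.17), Tax1bp3 (−0.85 ± 0.17), the serine synthesis enzyme Psph (−0.80 ± 0.14), Wdr46 (−0.78 ± 0.15), Ehd1 (−0.77 ± 0.15), Crlf2 (−0.72 ± 0.14) and citrate synthase, Cs (−0.64 ± 0.11). With the DBA comparison 7 higher features were shared (1.83 expected by chance), 4 lower (3.59) and 3 opposite (6.08). With no member past the threshold, lists of cortical (adjusted p = 0.00941), blood (0.00202), ribosomal (0.00126), oxidative phosphorylation (0.00126) and immediate early genes (0.00126) were lower in the NAc, and imprinted genes (0.00354) and the Xlr family (0.00379) higher; all had adjusted p = 0.416 to 0.681 with an estimated correlation. Without the samples in doubt the oxidative phosphorylation list no longer passed (adjusted p = 0.215) and the ribosomal list turned without passing (0.292). By fry, noradrenaline and serotonin genes alone were lower (adjusted p = 0.0266).

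Of the 3 mPFC and 2 NAc samples in that comparison, 1 each carried markers of the other region, and without the samples in doubt the count was 1750, of which 17 were shared with the 30. It was 0 without mPFC control 3, 14 without mPFC control 1, 10 without mPFC control 2, 8 without NAc control 1 and 3 and 182 without NAc control 2 and 4; it was 0 when the 2 groups were fitted alone, and 61 with quantile normalization, of which 36.1% were higher, against 56.7%. No feature passed with array weights or with the replicate number as a block. Without the samples in doubt 1 NAc control sample was left, which was assumed to vary like the other groups. Groups of 28.7% of features did not overlap, against 20% expected by chance.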

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

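The tests chosen only after the results were seen are those of the samples in doubt in the C57 NAc, and of C57 RNA, tissue share and near-identical family members for Xlr4.

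Of 128 values tested in the 4 groups of 4 samples (32 measures), 8 lay far from the other 3 samples of their group. By chance 5% of 128, or 6.4, would do so if the values were independent, which they are not. The values of C57 NAc RCF 1 and DBA NAc control 4 among them came from samples in doubt, so the count does not make these a matter of chance. C57 NAc RCF 1 stood apart with a tissue score of −0.86 (others 4.78 to 5.20), cortical markers at 0.94 (others −1.67 or less), striatal markers at 0.072 (others 2.85 to 3.20) and dopamine signalling genes at 0.30 (others 1.76 to 1.94). These 4 measures are not independent of one another. C57 NAc RCF 3 stood apart in oxidative phosphorylation genes, 5.13 against 4.87 to 4.89. DBA NAc control 4 had a strain score of 7.26 against 11.78 to 12.43. DBA NAc RCF 3 had a strain score of 11.99 against 12.44 to 12.48 and striatal markers at 1.25 against 2.80 to 3.04.

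Outside the main measurement, genes of the Y chromosome had a signal in DBA mPFC control 1, although all mice are labelled female. Ddx3y was 1.21, against −6.56 or less on all other arrays, and Eif2s3y was 1.92, against −5.11 or less. On 5 other arrays Eif2s3y was also well above background, at those lower values, and Ddx3y on none.

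The effect of RCF on some gene lists differed between strains or tissues by an interaction test (camera with the preset correlation), and none of these differences held with an estimated correlation. Between the strains, oligodendrocyte markers (adjusted p = 0.000667) and vascular markers (adjusted p = 0.0216) differed in the mPFC, lower in DBA, each with adjusted p = 0.948 with an estimated correlation; without the samples in doubt, among them DBA mPFC control 1, neither passed (adjusted p = 0.661 and 0.481). In the NAc, chromatin genes (adjusted p = 0.0482, and 0.676 with an estimated correlation) and cortical markers (0.00284, and 0.865) were higher in DBA and striatal markers (0.0198, and 0.865) lower; without the samples in doubt only the chromatin genes passed (adjusted p = 0.0191, against 0.0926 and 0.537). Between the tissues of C57 mice, striatal markers were higher in the NAc (adjusted p = 0.00205, and 0.93 with an estimated correlation) and the Xlr family lower (0.0294, and 0.563), the former not without the samples in doubt (adjusted p = 0.382). Between the tissues of DBA mice, choroid plexus (adjusted p = 0.0335), immediate early (1.56e-05), microglia (0.00639), oligodendrocyte (0.00415) and vascular genes (4.45e-09) were higher in the NAc, each with adjusted p = 0.618 with an estimated correlation. Of these only the immediate early genes passed without the samples in doubt (adjusted p = 0.00353). Xlr4a and Xlr4b differed between the strains in the NAc by the unadjusted limma p of the interaction, a model value and not an exact test, of 0.0277 and 0.011, and neither passed adjusted over the list alone.

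The first pattern weighed is that of 6 samples with markers of another tissue, strain or sex than their labels. On a scale from 0 (mPFC) to 1 (NAc) over 11200 genes, the 4 C57 samples lay at 0.56 (mPFC control 3), 0.68 (mPFC RCF 1), −0.03 (NAc control 1 and 3) and 0.13 (NAc RCF 1). Exchanged tissue labels could explain 2 of these 4, which lay within 0.2 of the other tissue, and RNA of both tissues in a sample the other 2, which lay between 0.2 and 0.8; neither covers all 4, and which applies stays open. RNA of a C57 mouse has the values it needs in both samples labelled DBA, 2 of 2 lying under 0.5 between C57 and DBA over 1241 genes (0.25 and 0.17). No biological explanation was tested.

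The second pattern is the C57 NAc, where RCF and control differed in 179 features, most of them lower. RNA of cortical character in a larger share of the control samples needs most of the 179 to change in the direction of NAc minus mPFC in DBA mice. Of them 38.6%, or 69, did. This share cannot decide, because each group held a sample with the cortical marker profile beside samples without it. Features that differ strongly between the tissues therefore spread within both groups and could hardly pass. Of the 15 that were called between the tissues in DBA mice, 10 changed in that direction, and this explanation stays open. An effect of the place on the slide that the slides share is argued against: the larger median change on the mPFC slides was 0.182 of that in the C57 NAc. A gradient on the C57 NAc slide alone stays open. There control arrays sat in slide columns 1 and 2 and RCF arrays in columns 3 and 4, so place and treatment cannot be told apart. The samples in doubt may account for part of it, since without them the median change was 0.66 of the value with them and 7 features passed; the fall of the count does not speak for them, since it was 0 without RCF 4 alone, a sample in place, with the median change at 1.26 of 1.37. How much of the pattern remains without the samples in doubt stays open, as does a response of C57 mice to fostering, which was not tested.

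The third pattern is that of Xlr4a and Xlr4b, higher on average in RCF than in control DBA samples of both tissues. C57 RNA in the RCF samples is argued against by a lowest strain score of 10.68 among them, against a highest of 7.65 in C57 samples. With the tissue score as a covariate the Xlr4a change was 1.05 times as large or more, and the Xlr4b changes were 1.32 and 1.16. That fit used 1 slope for all 8 groups, and the score spread most within the C57 groups. It therefore cannot decide whether a different share of the 2 tissues lay behind the change in DBA mice, which stays open. Signal shared between near-identical family members could be the source, since 5 of 5 probes named Xlr3b, Xlr4a or Xlr4b were higher in both tissues, and cannot be told apart from a change of Xlr4 itself. Of 1400 regroupings, 68 had a mean Xlr4a difference as large as the real 1.30 (highest other 1.97), an exact p of 0.0486 that became 0.0729 after adjustment, so chance is not excluded for the 3 genes together. An effect of fostering in DBA mice stays open.

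Other splits of the samples show how often another grouping gave as many features. For the regions of DBA mice, of 35 splits only the real one did (11557, highest other 5215). That is the smallest share 35 splits allow, with no adjustment over the comparisons split, and the real split also separated the slides. Chance cannot be excluded for RCF in the C57 mPFC (28 of 35 splits as large, real 745 features at an unadjusted p under 0.05, highest other 5504) or in the DBA NAc (32 of 35, real 607, highest other 4035). Nor can it be for the interaction of strain and treatment in the mPFC (74 of 100, real 442, highest other 4281) or that of tissue and treatment in DBA mice (89 of 100, real 325, highest other 2649). The same holds for RCF averaged over strains in the mPFC (49 of 100, real 659, highest other 2989). Splits with several times the real count may reflect a structure of the samples other than treatment, which was not tested. Too few splits, 10 each, were possible for RCF in the DBA mPFC (4 as large, real 469, highest other 1178) and for the strains in the mPFC (1 as large, real 7358, highest other 3).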

How the results depend on the processing

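The tests added after the results were seen are all 31 arrays as separate replicates, the files as listed, leaving out the samples in doubt and the tissue score as a covariate, and every alternative for RCF averaged over the strains. Values are features past the threshold, or log2 changes for single genes, and for the Xlr family the values over all 14 comparisons that passed adjusted over the list alone (2 as reported). Under the stricter filter on dim probes all 15 results compared stayed within 1.5 times their value, or at 0, and with no filter 15 did. A slide as a random block was not run, because each slide held 1 strain and 1 tissue and the group means absorb it. Except where fewer samples or features or another test are the setting itself, the cause was not tested.

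Leaving out each sample in turn gave, for RCF against control, 0 to 1347 features in the C57 NAc, 0 to 12 in the C57 mPFC, 0 to 1 in the DBA NAc, 0 to 344 averaged over strains in the NAc and 0 to 3 in the mPFC. It gave 0 to 520 for the interaction of strain and treatment in the NAc and 0 to 1 in the mPFC, and 0 to 43 for that of tissue and treatment in C57 and 0 to 1 in DBA mice. Between the strains it gave 855 to 6728 in the NAc and 4339 to 6526 in the mPFC, and between the tissues of C57 mice 0 to 182. Where a group was left with 1 sample, that sample was assumed to vary like the other groups. This also held for the C57 NAc control group without the samples in doubt.

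Leaving out each sample also moved the sign of changes that had not passed: Xlr3b averaged in the NAc (−0.11 to 0.15), in the DBA mPFC (−0.083 to 0.91), in the strain interaction in the mPFC (−0.72 to 0.49) and in the tissue interaction in DBA mice (−0.21 to 0.78); Xlr4a averaged in the NAc (−0.15 to 0.26), in the C57 mPFC (−0.23 to 0.86) and in the tissue interaction in DBA mice (−0.91 to 0.50); and Xlr4b in the C57 mPFC (−0.44 to 0.58) and in the tissue interaction in DBA mice (−0.72 to 0.64). The Xlr4a change in the DBA mPFC was 0.74 without RCF 2 and 2.16 without RCF 1 and 3 (limma, over the list alone: adjusted p = 0.0486), and in the DBA NAc 0.81 without control 3 and 1.62 without control 4. With normexp these were 0.67 and 0.60.

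Quantile normalization gave 301 features for RCF in the C57 NAc, 61 between the tissues of C57 mice and 4 for the Xlr family, an Xlr3b change of −0.0044 averaged in the NAc, and ribosomal proteins higher instead of lower in the DBA mPFC (adjusted p = 0.887). Normexp with quantile normalization gave 347 for RCF in the C57 NAc, 77 between the tissues of C57 mice, 85 averaged in the NAc, 7 for the strain interaction in the NAc, 1 for the tissue interaction in C57 mice, 7 for the Xlr family, an Xlr4a change of −0.13 averaged in the NAc, and the same turn of ribosomal proteins (0.976). With no filter the tissue interaction in C57 mice had 1 feature. The median over probes gave 1 for the strain interaction in the NAc, 5 for the Xlr family and 0.26 for Xlr4a in the tissue interaction in DBA mice. With the matrix values, 22445 features were tested against 30163; there were 4894 features between the strains in the mPFC (4449 of the 5039 reported ones that could be tested) and 7587 between the tissues of DBA mice (7412 of 7772), 6 for the Xlr family and −0.010 for Xlr3b averaged in the NAc. An estimated correlation left 0 of 57 gene lists.

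With array weights there were 13055 features between the strains in the mPFC, 0 and 18851 between the tissues of C57 and DBA mice, 116 and 5 for RCF averaged in the NAc and mPFC, 11 each for RCF in the C57 mPFC and the DBA mPFC, and 5 for the Xlr family. Array weights also gave Xlr3b 0.26 in the strain interaction in the mPFC and −0.054 in the tissue interaction in DBA mice, where Xlr4a was 0.35 and Xlr4b 0.077, and Xlr4b 0.17 averaged in the NAc and −0.22 in the C57 mPFC. With only the groups compared, which leaves few samples to estimate the spread, there were 1437 features between the strains in the NAc and 0 between the tissues of C57 mice, for RCF averaged in the NAc and for RCF in the C57 NAc.

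The replicate number as a block gave 0 features between the tissues of C57 mice, −0.011 for Xlr3b averaged in the NAc and 0.28 for Xlr4a and 0.17 for Xlr4b in the tissue interaction in DBA mice; its other 13 counts stayed. The numbers gave no sign of pairing between the tissues of a strain and treatment. There the median correlation of arrays with the same number was −0.015 over genes, against 0.047 in other pairs. Genes are not independent replicates, and single pairs ran from −0.64 to 0.42, with 4 of 15 over 0.1, so pairing of some samples is not excluded. Between the strains, which cannot share a mouse, the median was 0.0144, against −0.00987 in other pairs.

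All 31 arrays as separate replicates gave 9785 features between the strains in the NAc, 1045 between the tissues of C57 mice, 219 for RCF averaged in the NAc, 1184 for RCF in the C57 NAc, 7 for the strain interaction in the NAc, 9 for the Xlr family and 0.014 for Xlr4a in the tissue interaction in DBA mice. The files as listed gave 1957 and 270 between the strains in the NAc and mPFC, 0 and 30 between the tissues of C57 and DBA mice, 9962 and 9618 for RCF averaged in the NAc and mPFC, 11497 and 8528 for RCF in the C57 NAc and mPFC, 5633 and 6428 in the DBA NAc and mPFC, 6392 and 4188 for the strain interaction in the NAc and mPFC, 7 for the tissue interaction in DBA mice and 8 for the Xlr family.

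The tissue score as a covariate gave 142 and 4609 features between the tissues of C57 and DBA mice, 43 for RCF in the C57 NAc, 7 for the Xlr family, and −0.070 for Xlr3b and −0.0024 for Xlr4a averaged in the NAc. Without the samples in doubt there were 2269 between the strains in the NAc, 1750 between the tissues of C57 mice, 7 for RCF in the C57 NAc, 5 averaged in the NAc, 5 for the strain interaction in the NAc, 3 for the tissue interaction in C57 mice and 7 for the Xlr family, with Xlr3b −0.17 in the tissue interaction in DBA mice and Xlr4b 0.057 averaged in the NAc. Without them these lists turned, none past the threshold: between the strains in the NAc cortical (adjusted p = 0.842) and striatal markers (0.741), between the tissues of C57 mice ribosomal proteins (0.292), for RCF in the DBA mPFC immediate early genes (0.676) and striatal markers (0.84), and in the tissue interaction in DBA mice choroid plexus (0.465) and oligodendrocyte markers (0.836).

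Of the other values, under leaving out each sample 667 stayed on their side of the threshold with the same direction, 186 were weaker and 4 stronger. Array signal over background limits genes near the floor: changes of genes with no array of a group well above background are given as lower bounds or not at all, and those with 1 of 4 are not measured folds.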

Other observations

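DBA NAc samples fell into a lower and a higher range of the tissue score: control 1 (2.98), RCF 3 (3.29) and RCF 4 (3.06) lay below RCF 2 (4.04), control 4 (4.65), control 2 (5.04), RCF 1 (5.12) and control 3 (5.24). The low scores were not of 1 kind. Striatal markers were low in control 1 (1.17) and RCF 3 (1.25) but not in RCF 4 (2.80), whose cortical score (−0.25) was the highest of the DBA NAc samples. Some markers of the septum and neighbouring regions were higher in the DBA NAc than in the mPFC, among them Lhx8, Gbx1 and Nkx2-1, each well above background on 1 of 4 mPFC arrays. Other members of that list did not pass or were lower, and the list did not pass with an estimated correlation.

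Both control samples of the C57 NAc are averages of 2 near-duplicate arrays, and the 2 samples differ in tissue score (−1.40 and 4.75). The 2 DBA mPFC samples made of 2 arrays each had tissue scores of −1.88 and −1.99.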
